A study of Mus musculus with 20 samples.

How the data were processed

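RNA-seq was deposited for 20 libraries of jejunal epithelium from female mice, in 4 groups: 5 control and 7 double-knockout (DKO) libraries in an acute model, and 3 control and 5 DKO libraries in a prolonged model. Per the labels, the acute libraries came from 7 days after ablation was induced and the prolonged ones from 5 months after it, and the series design names crypt epithelium. The labels describe the libraries as biological replicates, and the acute labels carry an animal number each. Poly(A) RNA libraries were made with a kit from NEB, per the labels' protocols.

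The submitters' processing notes name FastQC 0.11.5, STAR, SAMtools 1.9, bedtools 2.27.1, featureCounts 1.6.2 and DESeq2, and the mouse build mm9, without giving a role or order for each. The authors deposited 1 table per time with a row per gene symbol. The deposited values per library are CPM, reads per gene scaled to an equal total in every library, as the equal column sums show, with no scaling for composition. The tables also hold the authors' DESeq2 columns: a mean normalised signal over all libraries, a log2 fold change with its standard error, and a p-value with an adjusted p-value, per the file headers. There were 17294 gene names at the acute and 16195 at the prolonged time. Of the acute names, 24 had been turned into dates and 2 occur more than once; date-like names were left out of comparisons between times. A further 8 columns (test statistics, the authors' calls and group means) were not used. The reference at hand is of another mouse build, so no genomic positions are given and genes are named by the symbols of the tables. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart, and reads of near-identical genes such as the defensins may be divided in an unknown way.

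Every CPM value was a whole multiple of 1 step per library, within 0.01 reads, in 100% of values of every library, so whole reads could be recovered. For prolonged control 3 the step lies near a power of 10, which makes this evidence weaker for that library. Reads in genes came to between 15435100 and 26549500 in acute controls, 19134300 and 26586000 in acute DKO libraries, 9914740 and 23181600 in prolonged controls and 12560800 and 20612200 in prolonged DKO libraries. DESeq2 1.42.0 run on these reads gave the authors' fold changes within 3.41e-08 and the same 2344 and 2091 calls. Counts of the 44 pairs of libraries within a group differed by between 6.49 and 148 times the sampling variance, so all 20 libraries were counted as separate samples.

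CPM are not counts, so the main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(CPM + 1), fitted to each time alone with no covariate. Genes were tested where CPM reached 0.5 in at least 5 acute or 3 prolonged libraries, which left 13601 and 13316 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(CPM + 1) scale, DKO minus control, which understates changes of low genes. The change of the effect between times was the difference of both log2 fold changes over the root of their summed squared standard errors, on the 13088 genes tested at both times. The original plan named edgeR's quasi-likelihood test (edgeR 4.0.16) in 1 model for this comparison if whole reads could be recovered, and this condition was met. The use of limma here departs from that plan, because the deposited values are CPM. The planned edgeR test was run as an alternative, and its count is given beside the result.

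Apart from the test between times, the tests, the rule for named genes and 28 gene lists of cell types, pathways and complexes were fixed beforehand. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists; camera with an estimated correlation and fry were alternatives. A list score is the mean log2(CPM + 1) of its measured members in a library. Exact permutation tests of the scores over every split of the libraries, two-sided, were added after the camera results were seen. The scores carry no scaling for composition, and these tests were not repeated with it. For the interaction, splits of the unaltered values were planned first, but they left the genotype effect common to both times in the spread within the drawn groups and so could not test chance. They were replaced, after their result was seen (5 genes, highest other 1), by splits with that common effect removed from each gene. For shares of crypt, villus and immune cells, differences between list scores were tested. Whether any member of the compared list moved as far as the median of the list to be explained was counted after those tests. This count has no error across libraries, so it is given as a description and decides no share. The rule for named genes takes both targeted genes, the 6 largest rises and 6 largest falls among called genes whose groups do not overlap and whose higher group averages at least 1 CPM, 2 members with the smallest p of each list with a called member, a called member of the other direction, 4 interaction genes per direction, and the 6 genes with the smallest larger p at both times. Of the genes the rule takes from lists, those of the called lists are mostly named, and the rest are given as counts. Of the lists' members, 8 are shared by the stem cell and Wnt target lists and 1 each by a few other pairs.

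Alternatives chosen before the data were examined were edgeR with TMM factors, as the plan named it, edgeR with other scaling factors, DESeq2 and limma-voom with quality weights. Others were other filters, thresholds and pseudocounts of 0.5 and 5, each library left out in turn, the replicate number as a block, blocks of acute animals with numbers within 10 of each other, and 1 model over the 4 groups. Added after seeing the data were limma and camera on CPM divided by TMM factors, fits without acute DKO libraries 3 and 4, a limma model over the 4 groups for the interaction, and the cell cycle score as a covariate. For genes called at both times, edgeR with TMM factors was also added then, as was each library left out, the latter for their correlation too. The cell cycle score did not overlap between genotypes at either time, so a fit with it as a covariate cannot separate it from genotype. Directions and calls of that fit are given without a conclusion.

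The tests were tried on simulated counts made from the real means, library totals and dispersions, with a seeded set of genes changed by known folds. In the acute simulation, 52.2% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 100% of those changed 4-fold were called, with 12 false calls among 13582 genes. The prolonged simulation gave 65.2%, 80.6% and 96.9%, with 9 false calls among 13255 genes. The interaction simulation gave 43.3%, 78.8% and 92.2%, with 6 false calls among 13013 genes. Camera called 5 of 5 lists shifted 1.5-fold at each time and 0 of the unshifted lists; the simulated genes were uncorrelated within lists, unlike real ones.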

Results

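Gene expression was measured by RNA-seq in jejunal epithelium of control mice and of mice in which Kdm6a and Kdm6b, which encode demethylases of histone H3, had been ablated (DKO). The acute groups had 5 control and 7 DKO libraries and the prolonged groups 3 and 5. Between 9914740 and 26586000 reads per library lay in genes, with the fewest in prolonged control 3. Values are CPM as mean ± SD, and log2 fold changes (DKO minus control, on the log2(CPM + 1) scale) with standard errors from limma-trend.

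The targeted genes were lower in every DKO library than in every control library of the same time. Kdm6a was 66.1 ± 6.62 CPM in acute controls (n = 5) and 42.6 ± 2.73 CPM in acute DKO libraries (n = 7), and 76.2 ± 5.95 (n = 3) and 49.1 ± 3.93 CPM (n = 5) at the prolonged time. Kdm6b was 101 ± 6.71 and 70.4 ± 8.87 CPM at the acute time, and 102 ± 3.85 and 76.3 ± 4.98 CPM at the prolonged time. By limma, Kdm6a changed by -0.62 ± 0.07 and -0.62 ± 0.07 (adjusted p = 0.000145 and 0.000239), and Kdm6b by -0.53 ± 0.08 and -0.42 ± 0.06 (adjusted p = 0.00132 and 0.000910). These values per gene also count reads outside a deleted part, so they do not measure how complete the ablation was.

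**Figure D1:**
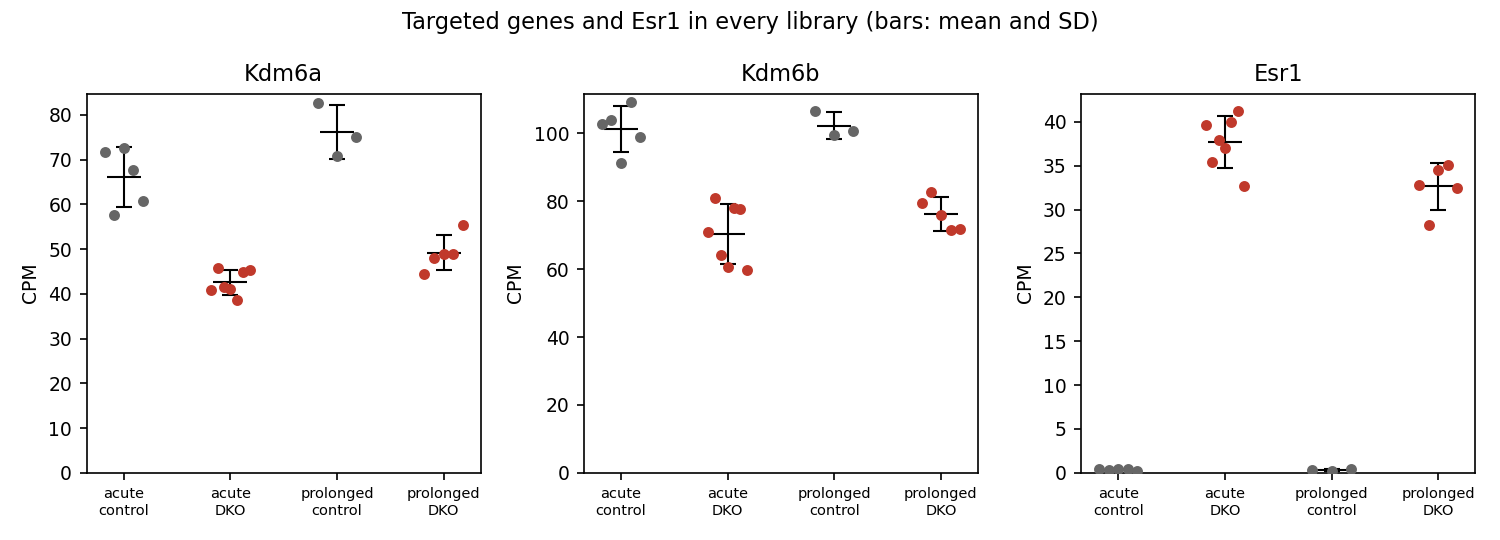
CPM of Kdm6a, Kdm6b and Esr1 in each library (points), with the mean and SD of each of the 4 groups (bars). Kdm6a lay between 38.5 and 45.7 CPM in acute DKO libraries and between 57.7 and 72.6 CPM in acute controls; Esr1 lay between 28.3 and 41.2 CPM in DKO libraries and at 0.454 CPM or less in controls.

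The first comparison asked which genes differed 7 days after ablation. The largest rise among the named genes was in Esr1, the estrogen receptor alpha, from 0.363 ± 0.0946 CPM in controls to 37.7 ± 2.93 CPM in DKO libraries (log2 fold change 4.83 ± 0.09, adjusted p = 2.51e-13). Whether these reads come from the gene itself is taken up below. Gml, Popdc3 and Kdelr3, which encodes a retrieval receptor of the endoplasmic reticulum, rose by 2.02 ± 0.45, 1.74 ± 0.20 and 1.52 ± 0.16. The interferon-induced oligoadenylate synthetase genes Oas2 and Oas3 rose by 1.48 ± 0.22 and 1.41 ± 0.16. Kcnk10, a potassium channel gene, fell from 21.6 ± 0.769 to 1.89 ± 0.420 CPM (-2.98 ± 0.11), and Mep1a, a brush-border metalloprotease gene, from 85.5 ± 12.8 to 11.9 ± 5.32 CPM (-2.84 ± 0.24). Evpl, the water and glycerol channel gene Aqp3, Paqr5 and the colipase gene Clps changed by -2.33, -2.32, -2.18 and -2.14. By limma, these genes had adjusted p of 0.00927 or less. The log2(CPM + 1) scale understates changes of low genes, so the order of these genes depends on it. In the authors' DESeq2 values the changes were larger for Gml (4.82) and Paqr5 (-4.45) and smaller for Mep1a (-2.74), Aqp3 (-2.25) and Clps (-1.94).

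Cell cycle genes fell at the acute time in 28 of 28 members, with a median of -0.64. The replication clamp gene Pcna went from 101 ± 8.25 to 66.4 ± 6.15 CPM (-0.60 ± 0.07), and the replicative helicase gene Mcm7 changed by -0.68 ± 0.07. Camera gave the list an adjusted p of 1.30e-18, against an adjusted p = 0.422 with an estimated correlation. The list score lay below every control in 7 of 7 DKO libraries (exact permutation p = 0.00126, the smallest that 792 splits allow; adjusted over 28 lists, 0.0354). Of the 28 list scores, 5 passed after adjustment (goblet and pancreatic acinar genes too, each lower, with exact p = 0.00884, adjusted 0.0495), against 10 with an exact p under 0.05. The pancreatic acinar score rests on only 3 measured members of 12, of which 1 was called. Whether these 5 scores pass with scaling for composition was not tested. Paneth cell genes, of the antimicrobial cells of the crypt base, fell in 14 of 19 measured members, or 18 adjusted over the list alone, with a median of -1.41. The matrix metalloprotease gene Mmp7 changed by -1.27 ± 0.19, and the secreted ribonuclease-family gene Ang4 by -2.04 ± 0.33, from 765 ± 409 to 177 ± 63.7 CPM. Their camera adjusted p was 6.05e-08, against an adjusted p = 0.523 with an estimated correlation. The Paneth score lay below every control in 7 of 7 DKO libraries (exact permutation p = 0.00379, adjusted 0.0495). Defensin and Ang genes have near-identical copies, so values of single members are uncertain; outside the defensins 9 of 10 members fell.

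Stem cell genes fell in 7 of 20 members at the acute time (13 adjusted over the list alone), among them Prom1 (-0.55 ± 0.09) and Slc14a1 (-1.79 ± 0.38). Wnt target genes, 8 of which are also on the stem cell list, fell in 3 of 20 (4 adjusted over the list alone), with Ephb3 at -1.01 ± 0.20 and Tnfrsf19 at -0.85 ± 0.18. Enteroendocrine genes fell in 6 of 27 (6 adjusted over the list alone), among them the hormone genes Ghrl (-0.82 ± 0.13) and Gcg (-0.89 ± 0.16). Camera adjusted p were 0.000810, 0.0378 and 0.0274, each with an adjusted p = 0.701 with an estimated correlation. The scores of these lists had exact permutation p of 0.0177, 0.0253 and 0.0265 (adjusted 0.0707, 0.0742 and 0.0742), so none passed after adjustment. Of all 13601 tested genes, 1641 were called lower. Acute DKO 3 and 4 had the lowest scores of all 12 acute libraries in these 3 lists and carried part of the falls. Without them the medians were -0.27 for stem cell genes (-0.44 with them), -0.18 for Wnt targets (-0.31) and -0.15 for enteroendocrine genes (-0.22), and of these camera called the stem cell list alone (adjusted p = 0.00143, 0.0928 and 0.256). Of the PRC2 and MLL3/4 complex genes, 8 of 22 fell, with Rbbp4 at -0.37 ± 0.06 and Rbbp7 at -0.35 ± 0.07, and Jarid2 rose by 0.31 ± 0.09 (camera adjusted p = 0.0349, adjusted p = 0.701 with an estimated correlation). Without acute DKO 3 and 4 the list's adjusted p was 0.106. Its score had an exact permutation p of 0.0177 (adjusted 0.0707). With the cell cycle score as a covariate, this list had a higher direction that missed the threshold (camera adjusted p = 0.284).

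Interferon response genes rose in 13 of 28 members at the acute time (17 adjusted over the list alone), with a median of 0.62. Ifit1, which encodes an inhibitor of viral RNA translation, went from 33.3 ± 6.50 to 74.5 ± 9.27 CPM (1.15 ± 0.12), and Rtp4 rose by 0.98 ± 0.12. The camera adjusted p was 2.37e-18, against an adjusted p = 0.422 with an estimated correlation. The interferon score lay above every control in 4 of 7 DKO libraries (exact permutation p = 0.00884, adjusted 0.0495). Absorptive enterocyte genes rose in 9 of 30 members and fell in 1 (13 and 1 adjusted over the list alone), with a camera adjusted p of 6.05e-08 and an adjusted p = 0.463 with an estimated correlation. The brush-border glucosidase gene Mgam rose by 0.68 ± 0.15 and Clec2h by 0.34 ± 0.08, and the trehalase gene Treh changed by -0.88 ± 0.25. With the cell cycle score as a covariate, camera gave the enterocyte list a lower direction (adjusted p = 9.78e-06). That score did not overlap between genotypes, so this fit decides no direction. The enterocyte score had an exact permutation p of 0.106 (adjusted 0.203). Dissociation and immediate early genes, which tissue handling can induce, rose in 4 of 15, with Fos at 0.76 ± 0.15 and Zfp36 at 0.31 ± 0.08 (camera adjusted p = 0.00263, adjusted p = 0.463 with an estimated correlation). This score was highest in acute DKO 3 and 4 (4.72 and 4.68), and without them 1 of 15 members rose, the median was 0.04 against 0.17, and camera did not call the list (adjusted p = 0.0928).

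Camera also gave a higher direction to the Hox, MHC class II, antimicrobial and inflammatory, immune cell and stromal lists at the acute time, with adjusted p between 0.00289 and 0.0361. Their adjusted p = 0.523 or 0.701 with an estimated correlation; 0 of their members passed limma's threshold, and the stromal median was 0.37. Without acute DKO 3 and 4 the stromal median was 0.04 and the antimicrobial median -0.17, against 0.23 with them, and camera called neither (adjusted p = 0.236 and 0.638), nor the Hox (0.106) and MHC class II (0.191) lists. The antimicrobial score was 6.03 and 6.10 in these libraries and 4.60 to 5.27 in the other DKO libraries. With the cell cycle score as a covariate, the stromal list stayed called, while the Hox (0.174), MHC class II (0.260), antimicrobial (0.284), immune cell (0.163), immediate early (0.775) and cell cycle (0.409, by construction) lists missed the threshold and the xenobiotic list was called lower (2.01e-06). Among the lists that camera did not call, goblet cell genes fell in 4 of 22, among them Spink4 (-0.75 ± 0.12), and the lectin gene Zg16 rose by 0.72 ± 0.08. Called members of the others numbered 2 lower for Notch pathway genes, 1 higher for tuft cells, 2 lower each for cell cycle inhibitors, p53 targets and cholesterol synthesis, 3 lower for the unfolded protein response, and 1 lower each for distal gut, enteric neuron and pancreatic acinar genes. Xenobiotic and imprinted genes each had 1 higher and 2 lower. Developmental regulators had Pax8 lower (-1.09 ± 0.18), and the regenerative list had Areg higher (0.88 ± 0.26) and Krt7 lower (-0.43 ± 0.10). Adjusted over the list alone at the acute time, the tuft cell, Hox, MHC class II, antimicrobial, immune cell and stromal lists had 0 higher and 0 lower each, the distal gut, cholesterol synthesis, enteric neuron and pancreatic acinar cell lists 0 higher and 1 lower each, the cell cycle inhibitor and p53 target lists 0 higher and 2 lower each, the unfolded protein response list 0 higher and 3 lower, the Notch pathway list 0 higher and 4 lower and the cell cycle list 0 higher and 28 lower. Adjusted over the list alone at the acute time, the developmental and regenerative lists had 1 higher and 1 lower each, the imprinted and xenobiotic lists 1 higher and 2 lower each, the goblet cell list 1 higher and 7 lower, the PRC2 and MLL3/4 list 2 higher and 10 lower and the immediate early list 4 higher and 1 lower. Under animal-number blocks camera gave the unfolded protein response a lower direction (adjusted p = 0.000689). For p53 targets and the unfolded protein response, the list median and camera's direction differed in sign.

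**Figure D2:**
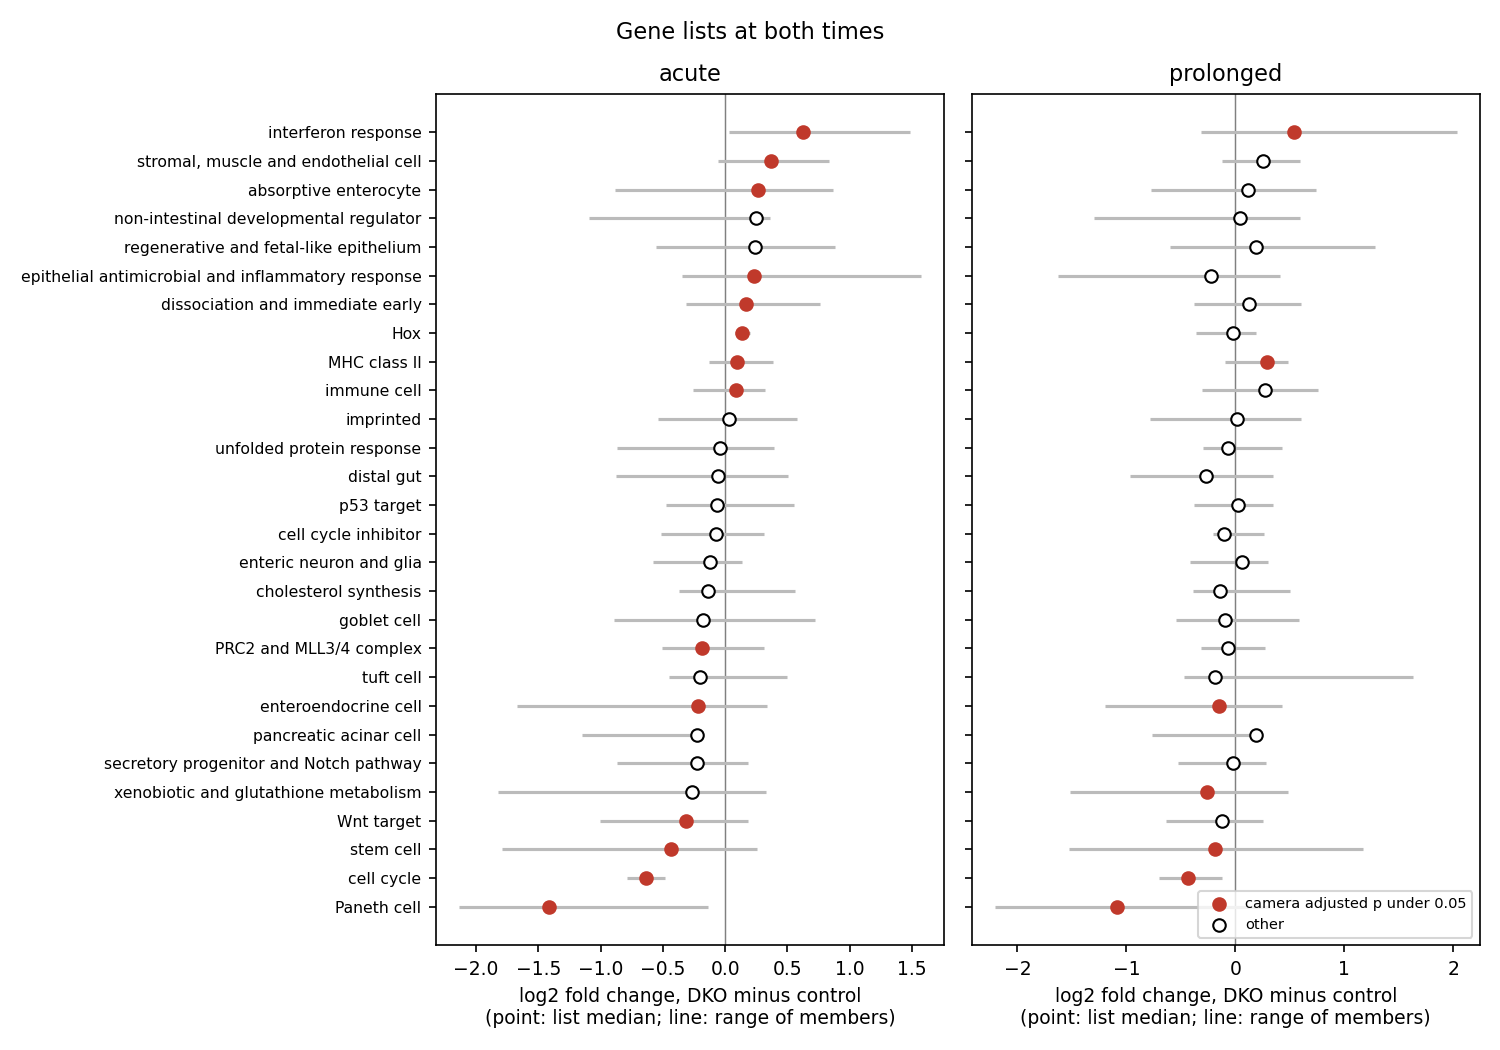
Median log2 fold change (points) and range of members (lines) for the 28 gene lists at the acute time (left) and the prolonged time (right), ordered by the acute median; filled points have a camera adjusted p under 0.05. Paneth cell genes had medians of -1.41 and -1.08 and interferon response genes of 0.62 and 0.54.

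In all, limma called 2035 of 13601 genes at the acute time, 394 higher and 1641 lower. That split depends on scaling: the median over all tested genes was -0.07 on the CPM scale, edgeR's relative log expression factors moved it by 0.10, and edgeR called 652 higher and 1069 lower with TMM factors, 722 and 1031 with relative log expression factors and 653 and 1103 with upper quartile factors. limma on TMM-scaled CPM called 701 and 1119, limma-voom 954 and 1472, and DESeq2 1040 and 1304, the last as in the authors' deposited table. On TMM-scaled CPM the Hox, MHC class II, antimicrobial, immune, stromal and PRC2 and MLL3/4 lists lost their camera calls (adjusted p = 0.173, 0.0743, 0.0812, 0.212, 0.0506 and 0.0601). Acute DKO libraries 3 and 4 stood apart on the first principal component (34.0 and 45.9, the other libraries between -28.0 and 12.1). Neither shared an animal-number block with a control, so in them a difference between blocks cannot be told apart from genotype. With animal-number blocks limma called 1419 genes, 1159 of them among the 2035. Without DKO 3 and 4, 1705 genes were called, and 6 lists in place of 14: stem, Paneth, enterocyte, cell cycle, interferon and immune cell. Without DKO 3 alone 7 lists were called, without DKO 4 alone 8, and without control 3, 1239 genes.

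Single acute libraries decided some of these calls, given here with the adjusted p of camera or limma without each. The enteroendocrine list was not called without control 2 (0.0731), control 5 (0.0645), DKO 3 (0.0786) or DKO 4 (0.0642), the Wnt target list without control 2 (0.130), DKO 3 (0.0584), DKO 4 (0.0642) or DKO 6 (0.0629), and the PRC2 and MLL3/4 list without control 1 (0.0595), control 4 (0.0554), DKO 3 (0.0695), DKO 4 (0.0596) or DKO 5 (0.0670). The Hox list was not called without control 1 (0.0787), DKO 4 (0.0865) or DKO 5 (0.107), the MHC class II list without control 2 (0.0698), DKO 3 (0.0565) or DKO 4 (0.0843), the antimicrobial list without DKO 3 (0.0786) or DKO 4 (0.0974), the immune cell list without control 5 (0.142), DKO 3 (0.226) or DKO 6 (0.0819), and the stromal list without DKO 3 (0.0565). The regenerative list was called without control 2 (0.0231), DKO 1 (0.0252), DKO 5 (0.0120), DKO 6 (0.0478) or DKO 7 (0.0379). Among genes, Clec2h lost its call without control 3 (0.0506), Zfp36 without control 1 (0.0614), control 2 (0.0539) or control 3 (0.0686), and Treh without control 2 (0.0631), control 3 (0.0697), control 4 (0.0693), control 5 (0.0622) or DKO 3 (0.0588). Areg lost its call without control 1 (0.0646), control 2 (0.0824), control 3 (0.104), control 4 (0.0603), DKO 1 (0.0679) or DKO 3 (0.0546), and Jarid2 without control 2 (0.0877), control 3 (0.107), control 4 (0.0682), control 5 (0.0811), DKO 1 (0.0616), DKO 2 (0.0580), DKO 3 (0.0802) or DKO 7 (0.0629). With edgeR and TMM factors Krt7, Areg and Treh were not called (adjusted p = 0.0730, 0.0615 and 0.0684).

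The second comparison asked which genes differed 5 months after ablation. Esr1 rose from 0.278 ± 0.117 to 32.6 ± 2.69 CPM (log2 fold change 4.72 ± 0.11, adjusted p = 2.28e-10). The fatty acid desaturase gene Scd1 rose from 1.22 ± 0.446 to 18.2 ± 8.44 CPM (3.02 ± 0.29), Popdc3 by 2.80 ± 0.12, the transporter gene Slco5a1 by 2.14 ± 0.20 and Amotl1, of the angiomotin family, by 2.10 ± 0.18. Kcnk10 fell from 18.1 ± 1.47 to 1.31 ± 0.120 CPM (-3.05 ± 0.11) and Fcgrt, the neonatal Fc receptor gene, from 105 ± 14.2 to 15.5 ± 2.53 CPM (-2.69 ± 0.12). The proton channel gene Otop3, the monocarboxylate transporter gene Slc5a8, Mep1a and the asparaginase gene Aspg changed by -2.60, -2.53, -2.51 and -2.46. Adjusted p by limma were 0.000113 or less for these genes. The interferon-induced GTPase gene Iigp1 was 0.929 ± 0.464 CPM in controls and 10.4 ± 10.8 CPM in DKO libraries (adjusted p by limma = 0.0260), and its call was lost in edgeR with TMM factors (adjusted p = 0.116), and without prolonged control 2, control 3 or DKO 5 (0.0685, 0.106 and 0.0593).

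Cell cycle genes fell in 23 of 28 members at the prolonged time (27 adjusted over the list alone), with a median of -0.44. Mcm3 changed by -0.58 ± 0.08 and the ribonucleotide reductase gene Rrm1 by -0.49 ± 0.08. The camera adjusted p was 1.06e-15, against an adjusted p = 0.704 with an estimated correlation. Paneth cell genes fell in 12 of 19 (14 adjusted over the list alone), with a median of -1.08; Ang4 changed by -2.21 ± 0.35, and the lectin gene Itln1 by -1.65 ± 0.30, from 2025 ± 124 to 700.5 ± 295 CPM. Their camera adjusted p was 2.58e-07, against an adjusted p = 0.856 with an estimated correlation. The cell cycle score lay below every control in 5 of 5 DKO libraries (exact permutation p = 0.0179, the smallest that 56 splits allow; adjusted 0.125), as did the Paneth score (exact permutation p = 0.0536, adjusted 0.150). After adjustment, 0 of 28 list scores passed at the prolonged time, against 6 with an exact p under 0.05. With 56 splits a score could pass only if many lists reached the smallest p, so this count shows little.

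Stem cell genes fell in 4 of 20 at the prolonged time and rose in 1 (11 and 2 adjusted over the list alone). Olfm4, a marker of crypt base stem cells, changed by -0.79 ± 0.09, from 1311 ± 91.5 to 761 ± 80.9 CPM, and Nrn1 rose by 1.17 ± 0.18. Enteroendocrine genes fell in 7 of 27 (9 adjusted over the list alone), with Reg4 at -1.20 ± 0.19 and Gcg at -1.10 ± 0.19, and Chga rose by 0.42 ± 0.11. Of xenobiotic and glutathione genes, 7 of 25 fell (9 adjusted over the list alone), with the quinone reductase gene Nqo1 at -0.62 ± 0.08 and Gstp1 at -0.37 ± 0.05, and Mgst1 rose by 0.49 ± 0.09. Camera adjusted p for these lists were 0.00328, 0.0151 and 0.00586, each with an adjusted p = 0.856 with an estimated correlation. With the cell cycle score as a covariate, the stem cell list had a higher direction that missed the threshold (camera adjusted p = 0.973). The enteroendocrine list was not called without prolonged DKO 4 (0.0509) and the xenobiotic list without prolonged control 2 (0.226), with camera's adjusted p in parentheses. Chga lost its call by limma without prolonged control 2 (0.103), control 3 (0.0813), DKO 1 (0.0574) or DKO 5 (0.0589), with adjusted p in parentheses.

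Interferon response genes rose in 18 of 28 members at the prolonged time (21 adjusted over the list alone), with a median of 0.54, a camera adjusted p of 2.75e-14 and an adjusted p = 0.704 with an estimated correlation. The antiviral tetherin gene Bst2 rose by 0.93 ± 0.10 and Oasl2 by 0.81 ± 0.10. The interferon score lay above every control in 5 of 5 DKO libraries (exact permutation p = 0.0179, adjusted 0.125). MHC class II genes, which present peptides to T cells, rose in 6 of 9 (6 adjusted over the list alone), with H2-Ab1 at 0.48 ± 0.09 and H2-Eb1 at 0.42 ± 0.08 (camera adjusted p = 0.00328, adjusted p = 0.856 with an estimated correlation). The immune cell list had 0 of 24 members past limma's threshold and a median of 0.27.

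**Figure D3:**
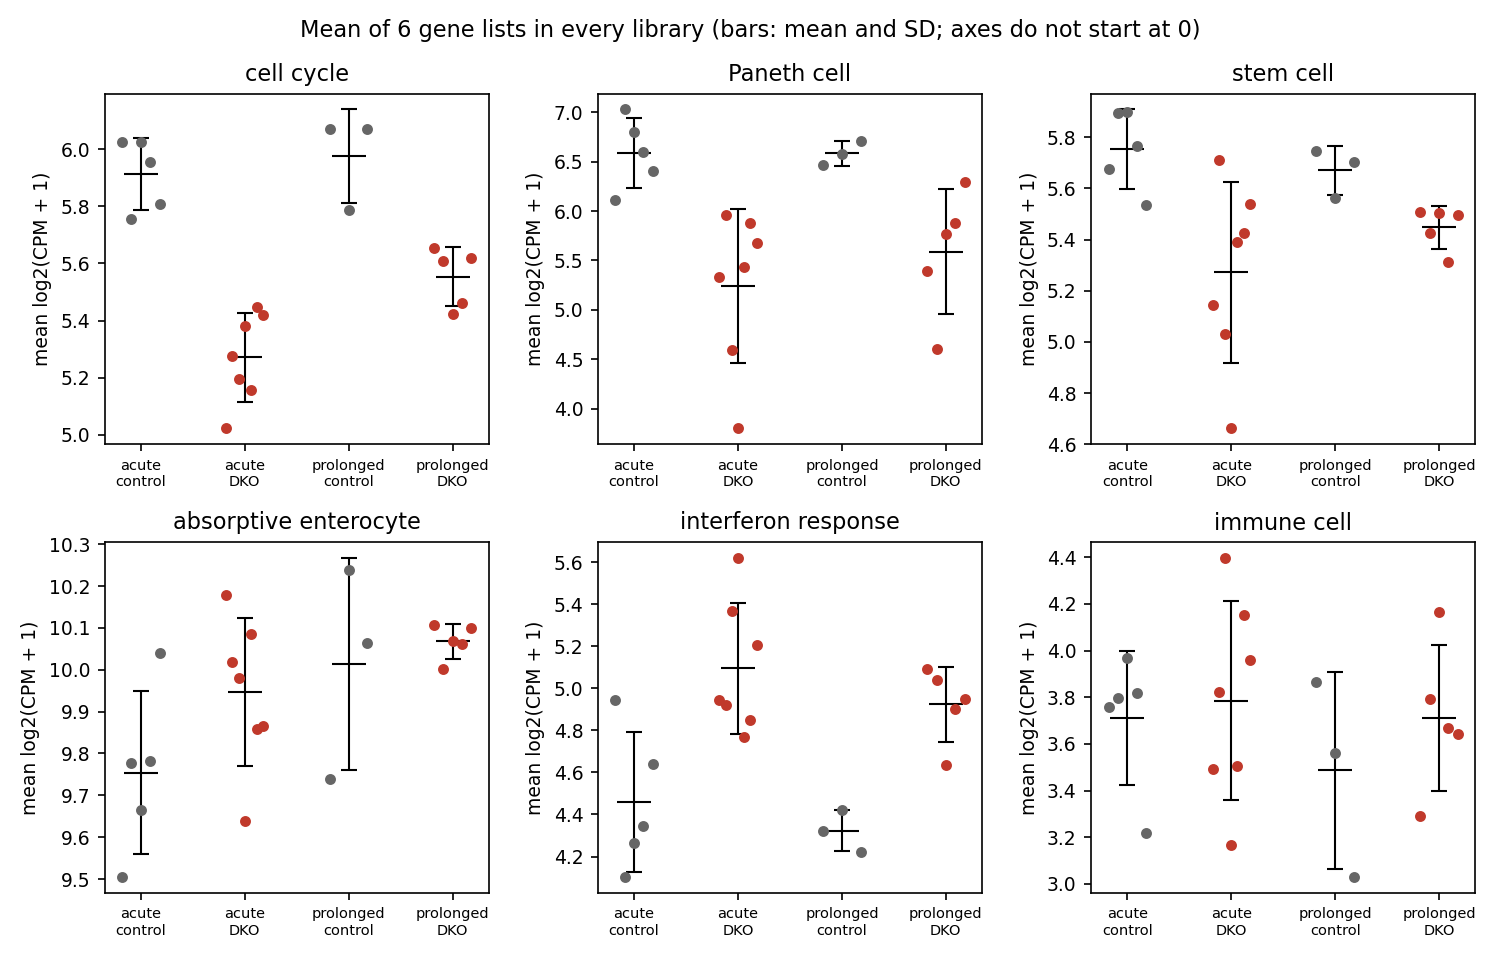
Mean log2(CPM + 1) of 6 gene lists in each library (points), with the mean and SD of each group (bars); axes do not start at 0. Cell cycle scores averaged 5.91 in acute controls and 5.27 in acute DKO libraries, and 5.98 and 5.55 at the prolonged time.

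Camera did not call the other lists at the prolonged time. With the cell cycle score as a covariate, which did not overlap between genotypes, it called 7 lists, of which the Paneth cell, interferon response and xenobiotic lists were among the 7 called without it. The enteroendocrine (adjusted p = 0.141), cell cycle (0.639, by construction) and MHC class II (0.264) lists then missed the threshold, as the stem cell list did, and the tuft cell (4.32e-05), antimicrobial (0.00688), distal gut (0.0392) and enterocyte (0.0392) lists were called lower, the last against its direction without the covariate. Called members numbered 2 higher and 4 lower for goblet cells, 3 higher and 1 lower for enterocytes, 1 higher and 3 lower for tuft cells, 1 higher and 2 lower for Notch pathway genes and 0 higher and 4 lower for Wnt targets. The antimicrobial list had 1 higher and 3 lower, among them Reg1 (-0.94 ± 0.15) and Nos2 (-1.62 ± 0.35), and the regenerative list 3 higher, among them Clu (1.28 ± 0.22), and 2 lower. The distal gut list had 3 lower, among them the bile salt transporter gene Slc51a (-0.96 ± 0.08), and 1 higher, and cholesterol synthesis had 3 lower. The imprinted and the PRC2 and MLL3/4 lists had 1 higher and 2 lower each. Cell cycle inhibitors, the stromal list and immediate early genes had 1 higher each, while p53 targets, developmental regulators, the unfolded protein response and pancreatic acinar genes had 1 lower each; Hox and enteric neuron genes had 0. Adjusted over the list alone at the prolonged time, the Hox, unfolded protein response, immune cell, enteric neuron and immediate early lists had 0 higher and 0 lower each, the p53 target, developmental and pancreatic acinar cell lists 0 higher and 1 lower each, the Wnt target list 0 higher and 6 lower, the cell cycle inhibitor and stromal lists 1 higher and 0 lower each, the Notch pathway list 1 higher and 2 lower and the tuft cell, antimicrobial and cholesterol synthesis lists 1 higher and 3 lower each. Adjusted over the list alone at the prolonged time, the distal gut list had 1 higher and 5 lower, the PRC2 and MLL3/4 and imprinted lists 2 higher and 2 lower each, the goblet cell list 2 higher and 6 lower, the absorptive enterocyte list 3 higher and 1 lower and the regenerative list 4 higher and 3 lower. For the Hox, developmental and pancreatic acinar lists, median and camera direction differed in sign.

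In all, limma called 1955 of 13316 genes at the prolonged time, 765 higher and 1190 lower, against 1015 and 1025 in edgeR with upper quartile factors. Without prolonged control 3, the library with the fewest reads, 1051 were called, and Nos2 was not (adjusted p by limma = 0.0578, and 0.0618 in edgeR with TMM factors). Without prolonged control 1, 12 lists were called in place of 7: the tuft cell, antimicrobial, distal gut, unfolded protein response and immune cell lists were added. Camera also called the tuft cell list without control 1 (0.000164) or DKO 3 (0.0282) and the immune cell list without control 1 (0.00578), control 2 (0.0229) or DKO 1 (0.00313), the enterocyte list without control 2 (0.000477), cholesterol synthesis without control 2 (0.0229) or DKO 1 (0.0195), immediate early genes without control 2 (0.0107) and Wnt targets without DKO 1 (0.0427). The antimicrobial, distal gut and unfolded protein response lists had adjusted p of 0.0158, 0.0397 and 0.0411 without control 1. In 1 model over the 4 groups 927 genes were called at the prolonged and 2989 at the acute time, the first without Olfm4, Reg4, Chga, Clu, Nos2 and Iigp1.

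The third comparison tested whether the effect of genotype differed between times. Both times had separate libraries and controls, so such a difference cannot be told apart from one between batches or sets of animals. At 13088 genes, 5 differences passed by limma, each higher at the prolonged time, and 887 had an unadjusted p under 0.05. Dcaf12l1, Slco5a1 and Serpine2, which encodes a secreted protease inhibitor, had log2 fold changes of 0.19 ± 0.19, 0.44 ± 0.18 and 0.17 ± 0.16 at the acute time, which missed the threshold, and rose by 1.77 ± 0.16, 2.14 ± 0.20 and 1.46 ± 0.15 at the prolonged time. Their differences were 1.58 ± 0.25, 1.70 ± 0.27 and 1.29 ± 0.22 (adjusted p = 0.00834, 0.00834 and 0.0161). In the authors' DESeq2 values Slco5a1 already rose at the acute time, by 1.58 (adjusted p = 0.0489). Dcaf12l1 and Serpine2 had 0.45 and 0.70 there (adjusted p = 0.450 and 0.393). The hormone gene Ghrl fell at the acute time (-0.82 ± 0.13) and had 0.26 ± 0.14 at the prolonged time, a difference of 1.08 ± 0.19 (adjusted p = 0.0237). Nrep, which the rule for named genes takes through the tuft cell list, differed by 1.13 ± 0.20 (adjusted p = 0.0237). In the other direction Tnk2, Tnfrsf21, Agrn and Palld had adjusted p of 0.266 or more. edgeR with TMM factors, the test that the plan named, called 0 genes (513 at an unadjusted p under 0.05). Of the alternatives, limma-voom called 2, none of them among these 5, and DESeq2 called 9, 3 of them among these 5. Without prolonged control 3 limma called 0 genes (698 at an unadjusted p under 0.05). It called 2 without acute control 2, acute control 3 or acute DKO 1, and 3 without acute DKO 7, prolonged control 2, prolonged DKO 1 or prolonged DKO 5. Without prolonged control 1 it called 9, and without prolonged DKO 4, 10. With limma's adjusted p in parentheses, Dcaf12l1 and Slco5a1 each lost the call without prolonged control 3 (0.0583), Serpine2 without acute control 2 (0.0515), acute control 3 (0.0684) or prolonged control 3 (0.0583), and Ghrl without acute control 2 (0.0515), acute control 3 (0.0705), acute DKO 1 (0.0507), prolonged control 2 (0.128), prolonged control 3 (0.207), prolonged DKO 1 (0.0663) or prolonged DKO 5 (0.0585). Nrep lost it without acute control 1 (0.0784), acute control 2 (0.0896), acute control 3 (0.105), acute control 4 (0.0623), acute DKO 1 (0.0577), acute DKO 7 (0.0834), prolonged control 2 (0.126), prolonged control 3 (0.142), prolonged DKO 1 (0.0663) or prolonged DKO 5 (0.0585). Serpine2 fell under the filter on low values, and was not tested, without acute DKO 1, 2, 5 or 7. Tnk2 was called without acute DKO 5 (0.0466) and Tnfrsf21 without prolonged control 1 (0.0236).

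Both responses were compared gene by gene. Of the 13088 genes, 223 were called higher at both times and 826 lower, 1049 in all. By limma 0 were called in opposite directions, against 1 each with DESeq2, edgeR with TMM factors and limma on TMM-scaled CPM. Independent lists of these sizes would share 22.3 higher and 146 lower genes. Fisher's exact test gave p = 3.63e-182 for the higher genes, and for the lower genes a p too small to be represented. This test takes genes as independent, which they are not, so its p does not measure replication across animals. The genes with the smallest larger p were Esr1, Kcnk10, Evpl, C4bp, Aspg and Mep1a. C4bp, a complement regulator gene, changed by -1.99 ± 0.12 and -1.98 ± 0.13, Evpl by -2.33 ± 0.15 and -2.19 ± 0.12, and Aspg by -1.96 ± 0.16 and -2.46 ± 0.12. The authors' DESeq2 values were -4.96 and -5.24 for C4bp, -2.35 and -2.28 for Evpl, and -2.32 and -3.95 for Aspg. Across genes, which are not independent replicates, the fold changes of both times had a Pearson correlation of 0.787 and a Spearman correlation of 0.678. Among the 2894 genes called at either time, 95.5% had the same sign at both. Without prolonged control 3, 661 genes were called at both times.

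**Figure D4:**
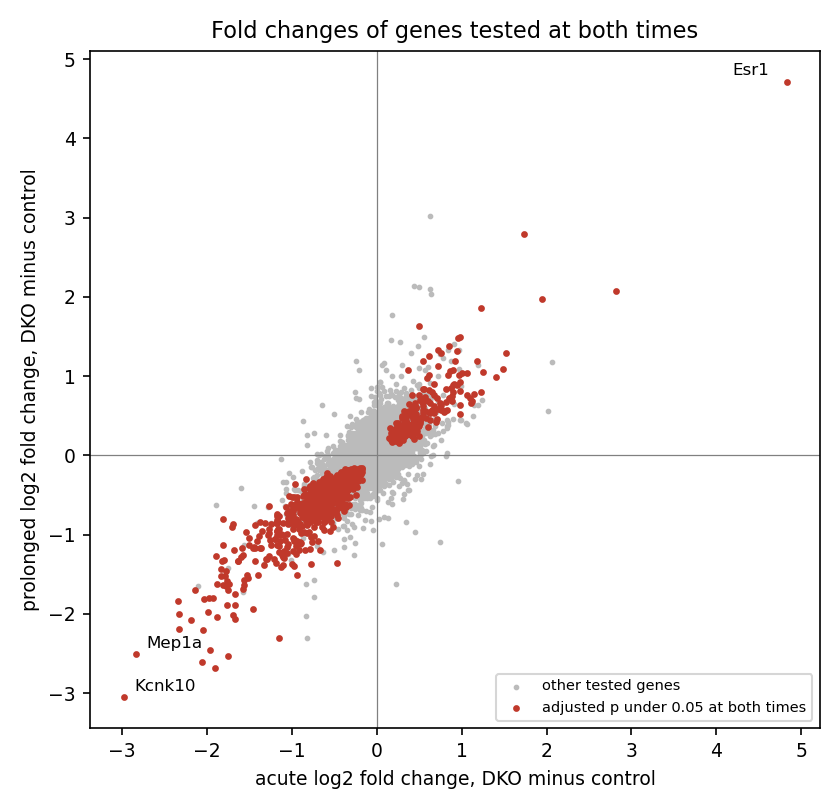
Log2 fold change (DKO minus control) at the acute time (x axis) and prolonged time (y axis) for the 13088 genes tested at both; red points passed limma's threshold at both times. The 1049 genes called at both in 1 direction lie in the lower left and upper right, with Esr1 at 4.83 and 4.72.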

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

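All tests of explanations in this part were chosen after the results were seen, except the splits of the libraries, which were planned before for all results but the interaction.

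Of 307 sets of values tested, 12 had a library far from the others of its group, against about 15.35 at a level of 0.05. That number does not allow for named genes having been picked partly for small p, which favours a small spread. Prolonged controls, with 3 libraries, were too few to test. In acute controls, Zg16 was 9.565 on the log2(CPM + 1) scale in replicate 2 against 9.78 or more in the others, and replicate 5 had the lowest Notch pathway score (4.238) and immune cell score (3.22). In acute DKO libraries, Mcm7 was 6.188 in replicate 7, Gstp1 was 7.464 in replicate 3, and replicate 4 had the lowest Guca2a (4.864) and xenobiotic score (4.562). In prolonged DKO libraries, replicate 2 had the lowest Zg16 (10.11), Reg4 (5.462) and pancreatic acinar score (2.898), and replicate 3 the lowest Kcnk10 (1.07) and Bst2 (4.018). For 5 genes the genotype effect differed between times by limma, by 1.699 for Slco5a1, 1.29 for Serpine2, 1.079 for Ghrl, 1.584 for Dcaf12l1 and 1.13 for Nrep.

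The splits argue against chance for limma's gene counts at each time, but do not exclude it. The real grouping gave the most genes in 1 of 100 splits at the acute time (2035, highest other 71) and in 1 of 56 at the prolonged time (1955, highest other 0). The acute splits were a drawn part of all, and the prolonged ones allow no smaller share than 1 of 56. Other splits hold the genotype effect in the spread within their groups, so 71 and 0 are not counts under chance alone. For both times together, the real pair among 100 paired splits gave 1049 genes and every other pair 0. As every other prolonged split called 0 genes, no other pair could share a gene, so this adds no test. For the interaction the splits were made after the genotype effect common to both times was removed from each gene, and the real grouping gave the most genes in 1 of 100 (5, highest other 2). This covers only the difference of 2 separate limma fits, and these splits replaced others whose result had been seen. With TMM factors edgeR called 0 (513 at an unadjusted p under 0.05), as did limma in 1 model over the 4 groups (652) and limma without prolonged control 3 (698). Chance cannot be excluded for the number of lists that camera calls: 19 of 100 acute splits gave 14 or more lists (highest other 17) and 41 of 56 prolonged splits gave 7 or more (highest other 15). Exact tests of single lists are given beside camera for this reason. They carry no scaling for composition and were not repeated with it. Acute lists near the threshold, such as goblet cell genes (exact permutation, adjusted p = 0.0495), may therefore depend on scaling. At the prolonged time the few splits leave those tests little room to pass after adjustment.

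The fall of Paneth cell genes may reflect fewer crypt cells in the DKO preparations, division of reads among defensins, or the 2 acute libraries that stand apart. Members outside the defensins had medians of -1.341 at the acute and -1.033 at the prolonged time, and without acute DKO 3 and 4 the acute list median was -0.998, which argues against those as the whole cause. Against the stem cell score the Paneth score differed by -0.87 at the acute time (exact permutation p = 0.00379, adjusted over 10 score differences 0.0379) and by -0.77 at the prolonged time (exact permutation p = 0.0893, adjusted 0.146, which missed the threshold). Against the cell cycle score it differed by -0.71 (exact permutation p = 0.0972, adjusted 0.146) at the acute time and -0.5724 (exact permutation p = 0.196, adjusted 0.218) at the prolonged time, which missed the threshold. As a description, 0 of 28 cell cycle genes fell as far as the Paneth median at either time (lowest -0.7917 and -0.70, medians -1.41 and -1.08). Of stem cell genes, 1 of 20 did at each time (lowest -1.79 and -1.53). A smaller share of crypt cells would lower stem cell, cell cycle and Paneth genes alike only if each list were equally confined to the crypt. This was not tested, and the log2(CPM + 1) scale understates changes of low genes. The acute difference shows that the Paneth score fell further than the stem cell score, but it cannot decide the share of crypt cells. A smaller share stays open at both times, as does an effect of the ablation.

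The rise of interferon response genes may come from more immune cells, more villus cells, the same 2 libraries, or the ablation. Without acute DKO 3 and 4 the median was 0.4777, which argues against those libraries. Set against the enterocyte score, the interferon score was higher in DKO libraries by 0.5468 at the prolonged time (exact permutation p = 0.0357, adjusted 0.107), which argues against villus cells there only before adjustment, and by 0.4434 at the acute time (exact permutation p = 0.117, adjusted 0.147), which leaves them open. Set against the immune cell score it was higher by 0.56 (exact permutation p = 0.102, adjusted 0.146) and 0.3767 (exact permutation p = 0.232, adjusted 0.232), which decides neither time. More immune cells would raise their own genes at least as much. At the acute time 0 of 27 immune cell genes rose as far as the interferon median of 0.62 (highest 0.3169, median 0.09). At the prolonged time 1 of 24 did (highest 0.76, median 0.27 against 0.54). These counts have no error across libraries and the score differences missed the threshold, so immune cells stay open at both times.

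Esr1 rose in all 12 DKO libraries to similar levels, and its effect differed between times by -0.1088. Reads from a transgene that carries part of the Esr1 sequence, such as an inducible recombinase, are a candidate source; the labels name none. Values per gene show no exon positions, so this and a change in the gene itself cannot be told apart. If the controls lack such a transgene, an effect of carrying it cannot be told apart from the ablation in any comparison here.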

How the results depend on the processing

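The alternatives on TMM-scaled CPM, fits without acute DKO 3 and 4, the limma model over the 4 groups for the interaction and the cell cycle covariate were chosen after seeing the data. So were list tests under animal-number blocks and, for genes shared by both times, edgeR with TMM factors, the block and left-out libraries. No named gene that passed in either fit changed direction; over the named genes, 3559 values kept their side of the threshold, 453 lost it and 25 gained it. An added limit on fold size (absolute log2 fold change of at least 1) left 163 acute, 194 prolonged and 100 shared genes, and an adjusted p under 0.01 left 870, 831 and 404, since both only narrow the threshold. The replicate number as a block left 947 acute, 528 prolonged, 284 shared and 0 interaction genes (1199 at an unadjusted p under 0.05); same-numbered libraries correlated by between -0.20 and 0.20 at the acute and between -0.24 and -0.16 at the prolonged time, and 0 of 8 controls correlated best with their own number, so the numbers do not pair the libraries. 1 model over the 4 groups left 927 prolonged genes and gave 2989 acute genes. For the other changes the cause was not tested. The interaction gave 2 genes at an adjusted p under 0.01, 2 at a mean CPM of at least 1, 9 with no filter, 2 with limma-voom, 9 with DESeq2 (3 of them among the 5), and 0 with a limma model over the 4 groups (652 at an unadjusted p under 0.05) and with edgeR under RLE, upper quartile and TMM factors (510, 539 and 513). The correlation between times was 0.6785 by Spearman and 0.8768 over genes called at either time. Lists called were 0 acute and 0 prolonged with an estimated correlation (2 and 1 at an unadjusted p under 0.05), and 4 and 3 with fry. By fry, the cell cycle (adjusted p = 0.000349 and 0.0272) and interferon response (0.0229 and 0.0189) lists were called at both times. Fry called the Paneth cell list at the acute time alone (adjusted p = 0.0335, against 0.193 at the prolonged time). The fry calls also held the distal gut list at both times (adjusted p = 0.0157 and 0.00441), which camera did not call in the main fit. At the acute time camera called 8 lists on TMM-scaled CPM, 6 without DKO 3 and 4, 9 under animal-number blocks (8 of them among the 14) and 8 with the cell cycle covariate (7 of them among the 14). With this covariate 7 prolonged lists were called, 3 of them among the 7. List directions reversed in 5 cases: the acute unfolded protein response under animal-number blocks (0.0006889), and with the cell cycle covariate acute enterocyte (9.776e-06), acute PRC2 and MLL3/4 (0.2837), prolonged stem cell (0.9725) and prolonged enterocyte (0.03922), all adjusted p. The covariate did not overlap between genotypes at either time, so the reversals under it decide no direction. Leaving out 1 library gave between 1239 (without acute control 3) and 2186 acute genes, 1051 (without prolonged control 3) and 1721 prolonged, 661 (without prolonged control 3) and 1103 shared, and 0 (without prolonged control 3) and 10 (without prolonged DKO 4) interaction genes. It gave 7 (without acute DKO 3; 8 without DKO 4) to 15 acute lists, 6 to 12 (without prolonged control 1) prolonged lists, and correlations of 0.722 to 0.806. Depth limits low genes most in prolonged control 3, at 9914740 reads.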

Other observations

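The tests in this part were chosen after the results were seen. Genes were also grouped by the stem of their symbol, into 220 families at the acute and 215 at the prolonged time. Every family that camera called at either time is given, with called members at the acute and then the prolonged time and both camera adjusted p over the families in brackets. At both times camera called a fall of replicative helicase genes (Mcm), lower in 8 of 10 and 8 of 10 (1.10e-05 and 0.000473), and nuclear pore genes (Nup), lower in 12 of 20 and 6 of 20 (1.10e-05 and 0.00179). It also called a rise of guanylate-binding protein genes (Gbp), which interferon induces, higher in 1 of 8 and 4 of 8 (0.00491 and 0.00179), and serine protease genes (Prss), higher in 2 of 10 and 4 of 10 (0.0315 and 0.0124). Which families were called differed between times, but the difference between times was not tested for them. Passing at the acute time and missing the threshold at the prolonged time were falls of the mitochondrial ribosome genes Mrpl, lower in 11 of 49 and 1 of 49 (0.00161 and 0.678), and Mrps, lower in 5 of 29 and 0 of 29 (0.0272 and 0.769), Rad genes, in 10 of 18 and 4 of 18 (0.00259 and 0.359), and RNA polymerase genes (Polr), in 7 of 28 and 0 of 28 (0.0104 and 0.751). The same was true of RNA exosome genes (Exosc), lower in 6 of 10 and 1 of 10 (0.0128 and 0.434), defensin genes (Defa), in 5 of 13 and 5 of 13 (0.0249 and 0.0511), and Haus genes, in 4 of 8 and 2 of 8 (0.0330 and 0.213). Collagen genes (Col) rose in 1 of 26 and 2 of 11 (0.00161 and 0.295), and apolipoprotein L genes (Apol) in 1 of 8 (0.0363), too few of which were measured at the prolonged time. Without acute DKO 3 and 4 the collagen median was 0.09 at the acute time (adjusted p = 0.229) and that of Gbp 0.28 (0.0693), neither of them called, too few Apol genes were measured, the other 10 families stayed called, and Cyb (0.0278, higher) and Psmd (0.0278, lower) were added. With an estimated correlation, these families had an adjusted p of 0.9985 at the acute and 0.995 at the prolonged time.

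Among clock genes, 1 of 10 that peak with Dbp and 1 of 5 that peak with Arntl passed limma's threshold at the acute time, and 2 of 9 and 1 of 5 at the prolonged time. Arntl fell by 0.94 ± 0.21 at the acute time (adjusted p by limma = 0.00804) and by 0.59 ± 0.11 at the prolonged time (adjusted p = 0.00396). Dbp rose by 1.19 ± 0.36 at the acute time (adjusted p = 0.0418), and Hlf by 1.33 ± 0.17 and Ciart by 0.69 ± 0.20 at the prolonged time (adjusted p = 0.000397 and 0.0418); the other clock genes missed the threshold. The score of genes that peak with Dbp minus that of genes that peak with Arntl was higher in DKO libraries by 0.8722 at the acute time (exact permutation p = 0.0429, adjusted over 10 score differences 0.107) and by 0.6843 at the prolonged time (exact permutation p = 0.0179, the smallest that 56 splits allow, adjusted 0.0893). The score of the genes that peak with Dbp differed by 0.58 and 0.47 at the acute and prolonged times (exact permutation p = 0.0556 and 0.0357), and that of the genes that peak with Arntl by -0.30 and -0.22 (exact permutation p = 0.0316 and 0.0357). After adjustment neither difference passed. Collection of the genotypes at other hours of the day is a candidate explanation that these values allow; the labels give no hour, and an effect of the ablation on the clock stays open and untested.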
